A study of Mus musculus with 6 samples.

How the data were processed

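Poly(A) RNA was measured in 6 libraries of mouse mesenchymal stem cells derived from bone marrow, 3 labelled control and 3 labelled as expressing immunoproteasome subunits. The values are raw counts of reads per gene, deposited without normalization and made, per the submitters' processing notes, from reads called with CASAVA 1.8.2, trimmed with Trimmomatic 0.35 and aligned to mm10 with TopHat2 2.1.0. The special entries at the end of the table are those of HTSeq. The HTSeq version, its strand setting and the gene annotation are not stated. If strand was not used, reads over exons shared with a counted gene on the opposite strand may be missing from both genes. The special entries hold such ambiguous reads, between 0.86 and 0.95% of the reads listed per library. A gene may still hold reads of an overlapping gene that the annotation lacks. The table held 23420 genes, of which 23053 matched by symbol a mouse annotation of the same build, used here for coordinates and overlaps, and 367 did not. It also held 5 special entries for reads assigned to no gene, which took 18.0, 19.8 and 18.0% of the reads listed in control replicates 1, 2 and 3 and 22.4, 20.0 and 21.9% in immunoproteasome replicates 1, 2 and 3. These entries were left out of the comparisons. A level of 3 counts, the limit that a count of 0 allows, corresponded to between 0.162 and 0.178 CPM in a single library.

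Counts were compared with edgeR 4.0.16 in R 4.3.3, with TMM normalization, the default filterByExpr filter (12477 genes kept), robust quasi-likelihood fits and a two-sided F-test of immunoproteasome against control. The p-values were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. Log2 fold changes are the fitted ones with a prior count of 0.125, and their SE comes from the same fit. Where a group had 0 counts, the fold was bounded against 3 counts over the group. Where it had 1 to 3 counts, the ratio of counts scaled by effective library size is given with its 95% counting interval. The immunoproteasome catalytic subunits Psmb8, Psmb9 and Psmb10 were also compared by an exact two-sided permutation test of log2 CPM, which cannot give less than 0.1 with 3 libraries per group.

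A set of 40 gene lists was tested with camera in limma 3.58.1, with a preset correlation of 0.01 between genes, and adjusted over the lists with at least 3 tested members. Camera was repeated with an estimated correlation, and fry, which asks whether the genes of a list move one way on balance, was run beside it. The comparison, the lists, the alternatives and the rule for naming genes were chosen before the data were examined. The rule takes the immunoproteasome catalytic subunits, the 12 genes with the largest rises and the 12 with the largest falls, the 5 genes with the smallest adjusted p, and up to 4 members of each list with the smallest adjusted p. The largest changes were taken among genes with an adjusted p under the threshold, at least 5 CPM in the higher group, no overlap between groups and no predicted or clone name. A further 7 lists were written after part of the values had been seen, and are described only in the closing observations.

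The alternatives were RLE size factors, scaling by total counts only, DESeq2 1.42.0, limma-voom, no filter beyond 1 count, a filter of at least 5 CPM in at least 3 libraries, the replicate number as a block, leaving out each library in turn, and a test against a 1.5-fold change. In the comparison of control replicate 2 with the other controls over a list, 0.5 CPM was added before the log. The pipeline was tested on simulated data of 12477 genes with 3 libraries per group, in which 50 genes were changed at each fold. It recovered 36, 42, 47 and 47 of the 50 genes changed 1.5-fold, 2-fold, 4-fold and 8-fold. Of 188 calls, 16 (8.51%) were false, a share above the adjusted p threshold of 0.05. Far fewer genes were changed there than the 9413 called in the data. The simulation therefore does not show how TMM or the error rate behave when most genes differ. Every pair of libraries was checked for duplicates and for distance. The median chi-square over genes, divided by that expected from counting alone, was between 1.34 and 1.49 within the immunoproteasome group, 1.70 between control replicates 1 and 3, 7.09 and 7.47 between control replicate 2 and those, and between 59.7 and 70.0 across groups, so no library repeats another. Permutation tests and figures used Python 3.11.15, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.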

Results

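Poly(A) RNA was sequenced from 6 libraries of mouse mesenchymal stem cells derived from bone marrow, the cultured stromal cells that can form bone, fat and cartilage cells. The labels put 3 libraries in a control group and 3 in a group in which subunits of the immunoproteasome were expressed. The immunoproteasome is the form of the 20S proteasome in which the products of Psmb8, Psmb9 and Psmb10 take the place of the constitutive catalytic subunits encoded by Psmb5, Psmb6 and Psmb7. The labels do not say which subunits were introduced or how, nor what the prefix AP2 in the titles of the control libraries stands for, so it is not known how the control cells were made. Counts assigned to genes summed to 18763101, 18305922 and 19176233 in control replicates 1, 2 and 3, and to 17519697, 16380048 and 17707443 in immunoproteasome replicates 1, 2 and 3. Levels are given as CPM, the normalised read count scaled to library size, as mean ± SD with n = 3 libraries per group unless a single library is named. The labels do not say that the libraries came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

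The comparison asks how the transcriptome of these cells differed once immunoproteasome subunits were expressed, in a study concerned with how well they cross-present antigen. All 3 transcripts of the immunoproteasome catalytic subunits rose in the immunoproteasome libraries, from low levels. Psmb8 (chromosome 17, 34197721 to 34201454, plus strand, mm10) rose from 9.65 ± 4.34 to 32.0 ± 1.63 CPM, a log2 fold change of 1.73 (SE 0.330, adjusted p = 0.00385, edgeR quasi-likelihood test). Psmb9 (chromosome 17, 34181987 to 34187764, minus strand) rose from 1.88 ± 0.892 to 11.0 ± 0.554 CPM, a log2 fold change of 2.54 (SE 0.292, edgeR adjusted p = 0.000113). Psmb10 (chromosome 8, 105935735 to 105938444, minus strand) rose from 9.88 ± 0.461 to 18.7 ± 0.697 CPM, a log2 fold change of 0.92 (SE 0.0778, edgeR adjusted p = 1.19e-05). All 3 of these protein-coding genes kept their call when adjusted over the list alone, and each was higher in 3 of 3 immunoproteasome libraries than in any control. An exact two-sided permutation test of the log2 CPM gave p = 0.1 for each gene, the smallest value that 3 libraries against 3 allow. Exons of Psmb9 overlap exons of Tap1 on the opposite strand, so reads over the shared part may be missing from both counts if strand was not used. The thymic subunit gene Psmb11 had 0, 4 and 6 counts in the controls and 7, 3 and 4 in the immunoproteasome libraries, too few to test.

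The controls were not alike at these genes. Psmb8 stood at 4.76 CPM in control replicate 2, against 11.1 and 13.1 CPM in control replicates 1 and 3, and Psmb9 at 0.850 CPM against 2.34 and 2.44 CPM. As a set the 3 subunits did not pass the camera test (adjusted p = 0.351), which compares a list with all other genes.

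**Figure D1:**
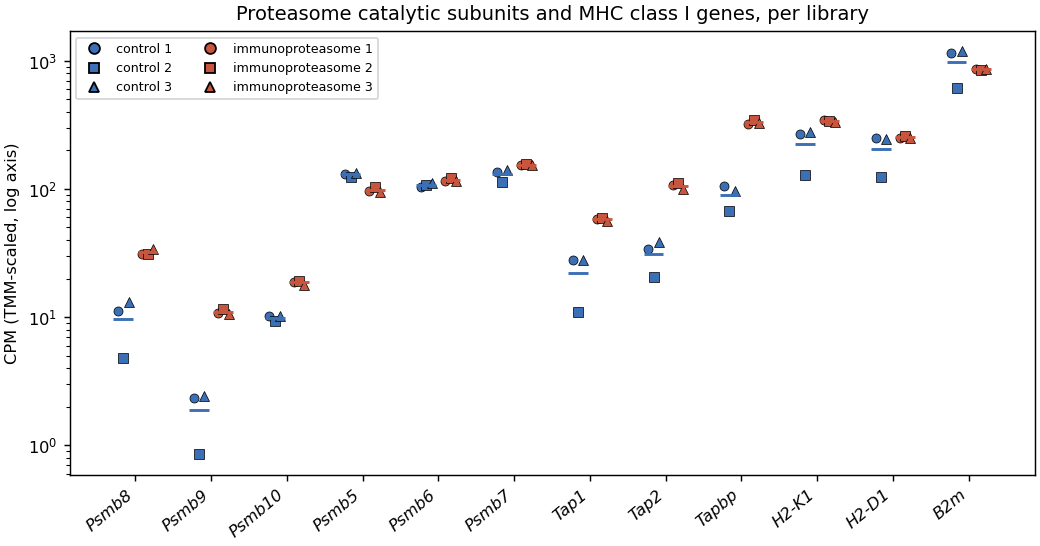
CPM on a log axis for proteasome catalytic subunits and MHC class I genes in each of the 6 libraries, with control libraries in blue, immunoproteasome libraries in red and a bar at each group's mean. Psmb8, Psmb9 and Psmb10 are higher in all 3 immunoproteasome libraries, while control replicate 2 (blue square) lies below the other controls for Psmb8, Psmb9 and the MHC class I genes.

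Other proteasome genes moved in both directions. Of the constitutive catalytic subunits, Psmb5 fell 1.32-fold from 129 ± 4.85 to 97.8 ± 4.72 CPM (edgeR adjusted p = 0.000177), while Psmb7 rose 1.19-fold (adjusted p = 0.0181) and Psmb6 1.09-fold (adjusted p = 0.0443). The call of Psmb7 was lost without immunoproteasome replicate 1 (adjusted p = 0.0510) or 2 (adjusted p = 0.0636), and that of Psmb6 without control replicate 1 (adjusted p = 0.122) or any immunoproteasome replicate (adjusted p from 0.0675 to 0.135), with the replicate block (adjusted p = 0.0893) and with DESeq2 (adjusted p = 0.0963). Over all alternatives the adjusted p ranged from 7.35e-05 to 0.0636 for Psmb7 and from 0.00206 to 0.135 for Psmb6. In the rest of the 20S core, 8 of 11 subunits rose and none fell, by small amounts, the smallest adjusted p belonging to Psma7 (1.34-fold), Psmb1 (1.29-fold), Psma5 (1.29-fold) and Psma1 (1.27-fold). The list of 19S regulator, activator and assembly genes was split, with 13 of 27 higher and 10 lower. Within it Psmd1 rose 1.66-fold, while the assembly chaperone Psmg2 fell 2.11-fold, the ATPase Psmc6 1.42-fold and the activator Psme3 1.63-fold. None of these lists passed the camera test (adjusted p = 0.926 for the constitutive subunits, 0.492 for the other 20S subunits and 0.926 for the 19S list). Adjusted over the list alone, the counts were the same in these lists, and in every other list except where a different count is given.

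Genes of peptide loading onto MHC class I split in both directions. Of 16 tested genes, 7 rose and 3 fell, and the list did not pass the camera test (adjusted p = 0.926). Tapbp, which encodes tapasin, rose 3.68-fold from 89.6 ± 19.6 to 330 ± 13.9 CPM, and the peptide transporter gene Tap2 rose 3.42-fold from 31.0 ± 9.18 to 106 ± 6.28 CPM. The members that fell were the endoplasmic reticulum chaperone genes Calr (2.84-fold), Canx (2.59-fold) and Pdia3 (2.06-fold, chosen after its values were seen). Calr is also a member of the unfolded protein response list described below, all of whose genes fell. Chosen after their values were seen, H2-K1, H2-D1 and B2m did not pass the threshold (edgeR adjusted p = 0.136, 0.382 and 0.521). In control replicates 1, 2 and 3, H2-K1 stood at 266, 129 and 276 CPM, below all immunoproteasome libraries (333 to 342 CPM). B2m stood at 1157, 613 and 1181 CPM there, against 852 to 861 CPM in the immunoproteasome libraries. H2-D1 stood at 251, 124 and 243 CPM, against 250 to 259 CPM. These class I genes come from a family of similar sequences. Reads without a unique alignment were set aside among the special entries (between 7.98 and 8.71% of the reads listed), so such reads may be missing here. Control replicate 2 again lay low, with a median log2 ratio of -0.72 to the other controls over the list, and without it 9 of the 16 genes rose and 5 fell. Among genes for uptake and cross-presentation, 9 of 23 rose and 12 fell (camera adjusted p = 0.551). Derl1, which encodes a channel protein of protein export from the endoplasmic reticulum, fell 4.28-fold, the translocon gene Sec61a1 fell 1.93-fold, the lysosomal Lamp2 fell 2.02-fold, and the scavenger receptor gene Scarb1 rose 3.13-fold.

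Across the transcriptome, 9413 of the 12477 tested genes (75.4%) differed between the groups, 4690 higher and 4723 lower in the immunoproteasome libraries. A change of at least 2-fold was seen for 1977 of the higher and 1383 of the lower genes. All 3 libraries of a group lay above all 3 of the other in 5040 genes that were higher and 4941 that were lower, together far above the 10% of genes that chance gives. The first principal component held 90.2% of the variance and separated the groups, and the second held 7.33% and separated control replicate 2 from the other controls. When libraries were scaled by total counts only, the median log2 fold change over all genes was 0.12, against 0.0020 with TMM, and the split became 5404 higher and 4005 lower. Without control replicate 2 the counts were 5320 higher and 5285 lower.

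Among the 12 genes with the largest rises was Alpl, which encodes the alkaline phosphatase of bone-forming cells and went from 1.91 ± 1.02 to 496 ± 17.2 CPM (log2 fold change 8.01, SE 0.279, edgeR adjusted p = 1.63e-06). Txnip, the thioredoxin-interacting protein gene, rose from 1.33 ± 0.247 to 106 ± 1.25 CPM, although its exons overlap an antisense gene. Ism1 rose from 0.771 ± 0.495 to 61.1 ± 1.73 CPM and Tmem26 from 0.793 ± 0.294 to 50.6 ± 2.07 CPM. Several others were nearly absent from the controls. Galnt9 had 1 count over the controls and 502 over the immunoproteasome libraries, a ratio of 505 after scaling (95% counting interval 90.3 to 20005). Ankle1 had 2 and 763 counts (ratio 384, interval 106 to 3178) and Col15a1 3 and 305 (ratio 102, interval 34.7 to 499). Draxin reached 15.9 ± 0.955 CPM, the carbonic anhydrase gene Car3 20.6 ± 1.40 CPM, Vsnl1 7.92 ± 0.174 CPM, Tnn 6.37 ± 0.376 CPM and Tgm5 7.40 ± 0.152 CPM, each from 15 or fewer counts over the controls. Their fitted folds rest on few control counts, and without control replicate 3 the log2 fold change moved from 6.86 to 8.82 for Draxin, from 6.18 to 7.81 for Car3 from 6.07 to 6.97 for Vsnl1 and from 8.52 to 10.39 for Galnt9. Without control replicate 1 it reached 6.68 for Tnn and 7.36 for Col15a1. Intervals and bounds of this kind cover counting error only.

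Among the genes that fell most, Ostn, which encodes osteocrin, went from 15.2 ± 0.872 CPM to 0 counts in the immunoproteasome libraries, at least 271-fold lower against a floor of 3 counts over the group. On the same floor Try5 was at least 141-fold lower, Acox2, an enzyme of bile acid synthesis, at least 135-fold, and the homeobox gene Alx1 at least 109-fold. The count ratio of control to immunoproteasome libraries was 1737 for Myom2 (interval 594 to 8427), 1307 for Hdgfrp3 (234 to 51659), 601 for H2-M10.1 (166 to 4967), 613 for the protease gene Ctsc (110 to 24240) and 546 for AI662270 (97.6 to 21612). Car6, a secreted carbonic anhydrase, fell from 241 ± 4.46 to 0.651 ± 0.0571 CPM and had the smallest adjusted p of any gene tested (4.90e-10, edgeR). The fitted log2 fold changes of Hdgfrp3 and Myom2 moved from -9.90 to -11.77 and from -10.59 to -11.41 without immunoproteasome replicate 1, and that of Ctsc from -8.81 to -10.68 without replicate 3. Exons of Hdgfrp3 overlap Tm6sf1 on the opposite strand. Gpr141 fell from 49.6 ± 14.2 to 0.0922 ± 0.0286 CPM. The next smallest adjusted p belonged to Ppp1r15a (1.32e-09) and to Colec10, Ddit3 and Ppef1 (1.75e-09 each). Colec10 rose from 2.50 ± 0.0559 to 93.7 ± 0.144 CPM, while Ppef1 fell by 7.08 on the log2 scale to 1.55 ± 0.135 CPM.

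Some of these low genes were uneven among the controls. Acta1, the skeletal muscle actin gene, stood at 344 and 372 CPM in control replicates 1 and 3 and at 0.794 CPM in control replicate 2, against 0.280 ± 0.0559 CPM in the immunoproteasome libraries. Its call (adjusted p = 0.0316) was lost without control replicate 1 (0.0702) or 3 (0.0705) and without any immunoproteasome replicate (0.0843 to 0.0892), and reached 0.694 with limma-voom. Alx1 (adjusted p = 0.0280) lost its call without control replicate 1 (0.0860) or 3 (0.0697) and with no filter beyond 1 count (0.0671). AI662270 (adjusted p = 0.0112) lost its call with limma-voom (0.138) and without immunoproteasome replicate 3 (0.0738), where its log2 fold change moved from -8.63 to -10.49. Over all alternatives the adjusted p of Acta1, Alx1 and AI662270 ranged from 2.06e-74 to 0.694, from 2.59e-31 to 0.0860 and from 1.31e-38 to 0.138, with the lowest value of each seen when control replicate 2 was left out. Libraries within the immunoproteasome group, and control replicates 1 and 3, differed little from each other. Control replicate 2 was at least 2-fold lower than the mean of the other controls in 466 of the 12477 genes and at least 2-fold higher in 147, whereas control replicates 1 and 3 were at least 2-fold apart in 94.

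Most genes of cell division rose. All 25 tested genes of mitosis and G2/M were higher in the immunoproteasome libraries, with a median log2 fold change of 3.09 (camera adjusted p = 2.29e-35; adjusted p = 0.153 with an estimated correlation), and all 25 also passed when adjusted over the list alone. Top2a, which encodes the DNA topoisomerase of dividing cells, rose 6.79-fold from 56.3 ± 4.42 to 383 ± 11.1 CPM. The kinase gene Cdk1 rose 4.30-fold from 34.3 ± 1.75 to 148 ± 3.07 CPM, Birc5 10.8-fold and the mitotic kinesin gene Kif20a 11.2-fold. Of 26 S phase and DNA replication genes, 24 rose, Mcm2 fell 1.18-fold (0 genes of the list fell with scaling by total counts only) and Cdt1 did not pass (log2 fold change -0.047; both named after their values were seen), with a median of 1.44 (camera adjusted p = 2.46e-16; adjusted p = 0.0227 with an estimated correlation). The ribonucleotide reductase gene Rrm2 rose 9.07-fold from 17.2 to 157 ± 3.74 CPM, Uhrf1 8.37-fold, the helicase subunit gene Mcm5 5.31-fold and the ligase gene Lig1 5.22-fold. Of the 40 fixed lists, this S phase list was the only one whose camera call held with an estimated correlation. The histone genes whose transcripts carry no poly(A) tail, which poly(A) selection captures poorly, gave 2 lower of 4 tested (Hist1h1c 2.18-fold and Hist1h2ac 3.30-fold; camera adjusted p = 0.561), and Hist1h1e and Hist1h2bc did not pass.

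**Figure D2:**
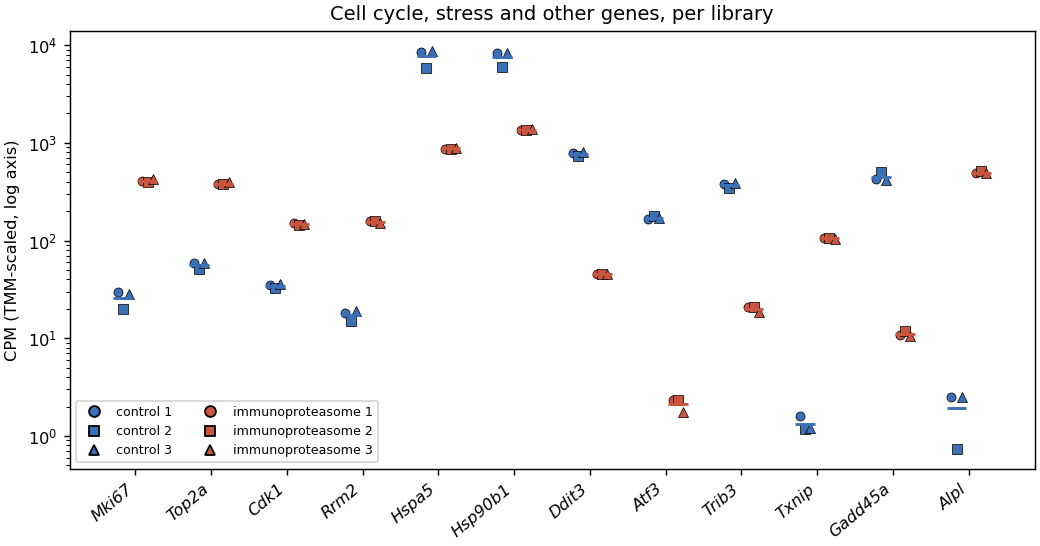
CPM on a log axis for 12 genes of the cell cycle, the stress response and other groups in each of the 6 libraries, some of them chosen after their values were seen, with control libraries in blue, immunoproteasome libraries in red and a bar at each group's mean. Control replicate 2 (blue square) lies below the other controls for Alpl, Mki67, Hspa5 and Hsp90b1; Mki67, Top2a, Cdk1, Rrm2, Txnip and Alpl are higher and the other 6 genes are lower in the immunoproteasome libraries.

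The unfolded protein response was lower as a whole. All 23 genes of this list, which restores folding capacity in the endoplasmic reticulum, fell, with a median log2 fold change of -2.03 (camera adjusted p = 8.78e-31; adjusted p = 0.153 with an estimated correlation), and all 23 passed when adjusted over the list alone. The transcription factor gene Ddit3, also known as CHOP, fell 17.1-fold from 776 ± 36.7 to 45.5 ± 0.282 CPM. Atf3 fell 80.1-fold from 171 ± 6.56 to 2.13 ± 0.339 CPM, the pseudokinase gene Trib3 18.5-fold and the phosphatase regulator gene Ppp1r15a 15.8-fold. The chaperone genes Hspa5 and Hsp90b1, chosen after their values were seen, fell from 7664 ± 1606 to 879 ± 13.8 CPM and from 7500 ± 1346 to 1366 ± 31.9 CPM. The heat shock list was split, with 7 of 15 genes higher and 6 lower (camera adjusted p = 0.637). Its cytosolic chaperone genes Hspb1 (2.66-fold) and Hspa1b (4.22-fold) rose, while the mitochondrial chaperonin genes Hspd1 (1.94-fold) and Hspe1 (2.03-fold) fell. Hspa1b has a near-identical neighbour, Hspa1a, and reads that align to both may have been set aside and be missing from its count.

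Lists of p53 targets and of oxidative stress genes also fell on balance. Of 18 p53 targets, 10 fell and 4 rose, with a median of -0.93 (camera adjusted p = 0.00111; adjusted p = 0.153 with an estimated correlation). Gadd45a fell 40.2-fold from 446 ± 46.4 to 11.1 ± 0.675 CPM, Plk2 12.4-fold, Sesn2 3.33-fold and Mdm2 2.82-fold. Gadd45a and Sesn2 are also known to respond to ATF4, the transcription factor of the integrated stress response. The cell cycle inhibitor gene Cdkn1a, chosen after its values were seen, did not pass (adjusted p = 0.0951), with 62.9 and 64.1 CPM in control replicates 1 and 3, 5.27 CPM in control replicate 2 and 9.70 ± 1.31 CPM in the immunoproteasome libraries. Of 25 NRF2 and oxidative stress genes, 16 fell and 4 rose (16 and 5 when adjusted over the list alone), with a median of -0.44 (camera adjusted p = 0.0204; adjusted p = 0.907 with an estimated correlation). The haem oxygenase gene Hmox1 fell 3.59-fold, the glutathione transferase gene Gsta4 16.9-fold and Srxn1 2.07-fold, while G6pdx rose 2.14-fold.

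Most type I interferon-stimulated genes were lower, while those of type II were split. Psmb8 and Psmb9 are themselves known to respond to interferon. Of 33 type I interferon-stimulated genes, 23 fell and 1 rose (Samd9l, log2 fold change 0.85, chosen after its values were seen), with a median of -1.30 (camera adjusted p = 0.0429; adjusted p = 0.907 with an estimated correlation). The call was lost without control replicate 1 (adjusted p = 0.0638) or 3 (adjusted p = 0.0783), and 2 genes rose without control replicate 1. Over the alternatives with the preset correlation the camera adjusted p ranged from 9.93e-08 to 0.0783. Without control replicate 2, 30 of 34 tested genes fell and 3 rose. Rsad2 fell 21.7-fold from 20.7 ± 5.15 to 0.953 ± 0.127 CPM, Oasl1 10.1-fold, Irf9 2.05-fold and Ifit2 1.84-fold, and without immunoproteasome replicate 2 the log2 fold change of Oasl1 moved from -3.33 to -4.18. Control replicate 2 was at least 2-fold lower than the other controls in 12 of the 33 genes. Of 18 type II interferon-stimulated genes, 5 rose and 6 fell (camera adjusted p = 0.926), or 10 fell without control replicate 2. Irf1, a transcription factor gene known to act on Psmb9 and Tap1, rose 2.11-fold from 22.6 ± 0.429 to 47.7 ± 1.44 CPM, and the proteasome activator gene Psme1 rose 1.46-fold, while the chemokine gene Cxcl10 fell 4.30-fold.

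Genes of inflammation and secreted factors moved in both directions, and none of their lists passed the camera test. Of 22 NF-kB and TNF response genes, 14 rose and 7 fell (adjusted p = 0.537). Zc3h12a rose 2.96-fold, whereas Csf1, the macrophage growth factor gene, fell 2.57-fold from 1059 ± 40.2 to 412 ± 1.06 CPM, Birc3 fell 5.37-fold and Tnfaip2 2.06-fold. Of 12 chemokine genes 7 rose and 4 fell (adjusted p = 0.520), with Ccl9 8.89-fold and Cx3cl1 1.66-fold higher and Ccl5 2.94-fold lower. Cxcl5 rose from 0.149 ± 0.0876 to 3.30 ± 0.330 CPM. Of 26 cytokine and growth factor genes 11 rose and 10 fell (adjusted p = 0.739), and Grem1 (9.76-fold) and the stress-induced Gdf15 (13.7-fold) fell. Of 15 immunosuppressive mediators 8 rose and 7 fell (adjusted p = 0.537). The ectonucleotidase gene Nt5e, which encodes the stem cell marker CD73, fell 8.18-fold from 21.0 ± 0.501 to 2.56 ± 0.146 CPM. Cd274, which encodes PD-L1, fell 3.29-fold, and the monocyte chemokine gene Ccl2 rose 2.23-fold. Of 11 genes of MHC class II and co-stimulation 4 rose and 5 fell (adjusted p = 0.926), with Vcam1 higher (57.2 ± 6.74 to 105 ± 3.07 CPM). Cd274, which fell, is also in this list, and the log2 fold changes of the list ran from -7.53 to 5.13. H2-DMa rose from 1.07 ± 0.0850 to 10.3 ± 1.55 CPM, and Icam1 had 2 counts over the controls and 82 over the immunoproteasome libraries (ratio 41.3, interval 11.1 to 347), its log2 fold change moving from 5.13 to 7.78 without control replicate 3.

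Genes of stromal identity and of the lineages these cells can form were also changed. Of 18 stromal markers, 12 rose and 5 fell (camera adjusted p = 0.292). Ly6a, which encodes the stem cell antigen Sca-1, rose 2.63-fold from 222 ± 7.46 to 584 ± 10.3 CPM, the tetraspanin gene Cd9 rose 3.49-fold and Itga5 1.83-fold. Nt5e, described above, is also in this list and fell. The log2 fold changes of the list ran from -5.00 to 4.04. Thy1, chosen after its values were seen, had 1 count in control replicate 1 and 0 in every other library, and was not tested. Of 11 osteogenic genes, 7 rose and 2 fell (adjusted p = 0.0530, and 0.0404 without control replicate 1, the lowest of a range to 0.0881 with the preset correlation). Besides Alpl, the transcription factor genes Runx2 and Dlx5 rose by 1.39 and 3.59 on the log2 scale, and Sp7 had 3 counts over the controls and 143 over the immunoproteasome libraries (ratio 48.0, interval 16.1 to 235), with a log2 fold change that moved from 5.42 to 6.27 without control replicate 1. The median of the osteogenic list was 1.39. It was 0.94 without control replicate 2, where 8 of 12 genes rose and 3 fell, and 0.56 with the filter of at least 5 CPM. Bglap2, not tested and chosen after its values were seen, had 20, 6 and 20 counts in the controls and 0, 0 and 1 in the immunoproteasome libraries. Of 10 chondrogenic genes, 7 rose and 1, Col11a2, fell 3.06-fold, or 8 rose and 2 fell without control replicate 2 (adjusted p = 0.198, and 0.0349 without that library, the lowest of a range to 0.275 with the preset correlation). Prg4 rose 6.95-fold and Sox5 8.28-fold, and Comp rose from 0.0737 ± 0.0302 to 1.06 ± 0.172 CPM. Of 11 adipogenic genes 4 rose and 5 fell (adjusted p = 0.926), with Cebpa 4.90-fold and Zfp423 13.8-fold higher and Klf15 21.8-fold and Cebpb 2.57-fold lower.

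Matrix genes rose on balance. Of 26 collagen and matrix glycoprotein genes, 20 rose and 2 fell, with a median of 1.05 (camera adjusted p = 0.04995; adjusted p = 0.907 with an estimated correlation). With the preset correlation the call was lost when libraries were scaled by total counts only (adjusted p = 0.0790, the highest of a range from 5.19e-06). Bgn rose 1.63-fold, Fbln2 3.31-fold from 310 ± 51.8 to 1027 ± 19.3 CPM and the crosslinking enzyme gene Loxl2 6.55-fold, whereas Fn1, the fibronectin gene, fell 1.53-fold. Control replicate 2 lay below the other controls over this list, with a median log2 ratio of -0.75. Of 18 matrix proteases and inhibitors 8 rose and 8 fell (9 and 8 when adjusted over the list alone; camera adjusted p = 0.739). Mmp23 rose 3.47-fold, and Timp3 and Adamts5 fell 2.39-fold and 2.19-fold. Of 16 contractile and YAP or SRF target genes 10 rose and 5 fell (camera adjusted p = 0.535). The members moved apart, with the smooth muscle myosin light chain gene Myl9 2.76-fold higher and the YAP targets Ankrd1 (3.69-fold), Lats2 (2.98-fold) and Amotl2 lower (Amotl2 by a log2 fold change of -0.85).

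**Figure D3:**
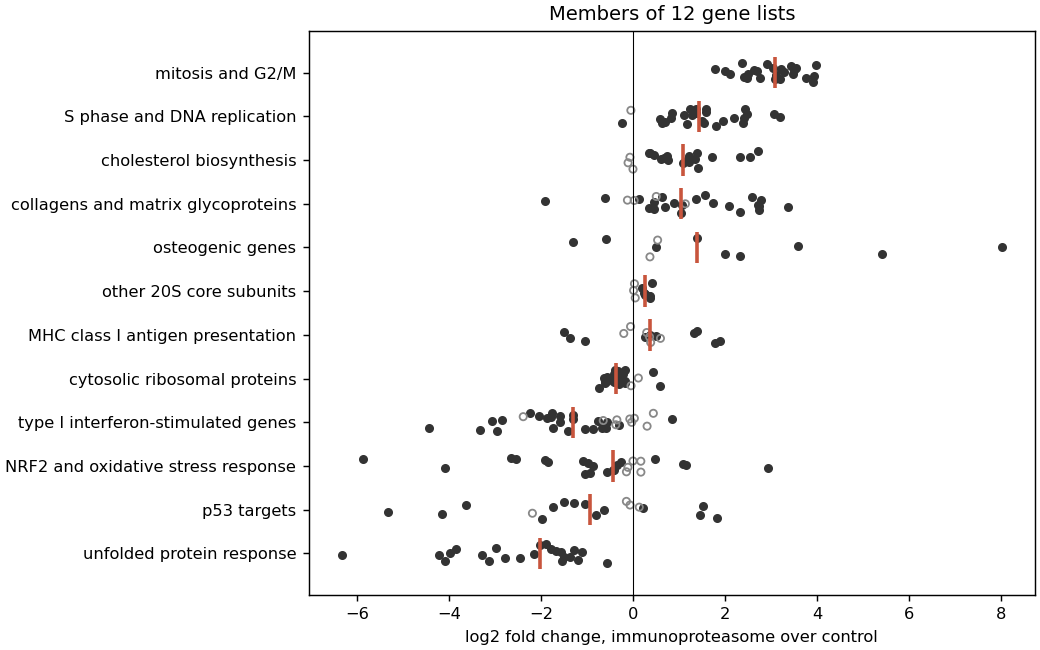
The log2 fold change of each tested member of 12 gene lists, immunoproteasome over control, with filled points for genes past the threshold, open points for the others and a red line at each list's median. The mitosis list has a median of 3.09 and the unfolded protein response list one of -2.03.

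Of 21 cholesterol synthesis genes, 18 rose and 0 fell, or 1 fell without control replicate 2, with a median of 1.09 (camera adjusted p = 5.54e-05; adjusted p = 0.907 with an estimated correlation). Idi1 rose 5.83-fold, Stard4 6.56-fold, Mvk 3.26-fold and Hmgcs1 2.34-fold from 46.5 ± 2.97 to 109 ± 0.983 CPM. Of 26 glycolysis and hypoxia genes, 14 rose and 8 fell (15 and 8 when adjusted over the list alone; camera adjusted p = 0.739), with Hk1, Tpi1 and Ldha 2.31-fold, 2.20-fold and 2.30-fold higher and Ndrg1 15.6-fold lower. Of 28 nuclear-encoded oxidative phosphorylation genes, 12 rose and 3 fell, where 6 fell without control replicate 2 and 16 rose and 1 fell with scaling by total counts only (adjusted p = 0.410), led by Ndufa4 (2.28-fold) and Ndufb8 (1.81-fold) with smaller rises of Sdha (1.46-fold) and Atp5a1 (1.36-fold). Of 17 ubiquitin and deubiquitinase genes, 5 rose and 8 fell (adjusted p = 0.537). Nfe2l1, the transcription factor gene that raises proteasome subunits, fell from 697 ± 11.6 to 333 ± 6.62 CPM, Nfe2l2 from 186 ± 5.82 to 103 ± 2.26 CPM and Ubb 1.51-fold, and Uchl1 rose 6.27-fold from 1.90 ± 0.521 CPM. Of 30 cytosolic ribosomal protein genes, 26 fell and 2 rose, with a median of -0.37 (adjusted p = 0.0619). Rpl10 fell 1.67-fold, Rps24 1.51-fold and Rpl4 1.49-fold, while Rps2 rose 1.49-fold. That list passed when any library except control replicate 3 was left out (adjusted p from 0.00319 to 0.0278), in a range up to 0.114 over the alternatives with the preset correlation. With an estimated correlation the camera adjusted p was 0.907.

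Few blood, endothelial and epithelial markers passed the filter on low counts. Of the macrophage markers 4 of 16 were tested, and Cd14 (3.47 ± 0.139 to 10.1 ± 0.0933 CPM), Csf1r (0.0742 ± 0.0325 to 0.866 ± 0.276 CPM) and Lyz2 (0.425 ± 0.134 to 1.09 ± 0.265 CPM) rose while Cd68 fell 3.67-fold (camera adjusted p = 0.537). The fall of Cd68 was 1.13 on the log2 scale without control replicate 2, against 1.88 with it, and its call was lost without immunoproteasome replicate 2 (adjusted p = 0.0547, the highest of a range from 2.50e-06). Of the 5 macrophage markers tested with a library left out, 2 fell without control replicate 2 or immunoproteasome replicate 1, and 0 fell without immunoproteasome replicate 2. Each of the lists below had fewer than 3 tested genes and no set test. The dendritic cell gene Zbtb46 fell 2.72-fold, the lymphocyte gene Lck 5.29-fold and the endothelial genes Vwf and Kdr 3.47-fold and 15.1-fold, and all were below 6 CPM. With a library left out up to 3 endothelial and 2 dendritic cell genes were tested, of which 1 each rose in some of these settings, as did 1 of 5 histone genes. The log2 fold change of Kdr was -3.31 without control replicate 2 and -4.56 without immunoproteasome replicate 3. The megakaryocyte gene Itga2b rose 2.34-fold from 2.55 ± 0.556 CPM and the epithelial gene Krt19 10.8-fold from 2.37 ± 0.180 CPM. The neutrophil gene Camp had 1 count over the controls and 83 over the immunoproteasome libraries (ratio 83.6, interval 14.6 to 3340), and the epithelial gene Krt14 had 1 and 44 (ratio 44.3, interval 7.55 to 1789). Leaving out a control changed the log2 fold change of Camp from 5.93 to 7.81 (replicate 2) and that of Krt14 from 5.02 to 6.89 (replicate 1). No mitochondrially encoded gene was among the genes counted.

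In 7 of these lists the median, the mean and the direction of the camera test did not share a sign. The medians were 0.12 for the constitutive catalytic subunits, 0.28 for the immunosuppressive mediators and 0.25 for glycolysis and hypoxia, with means of -0.012, -0.041 and -0.081, and camera ranked the first and second lower and the last higher. The medians were -0.053 for the heat shock response and -0.013 for the adipogenic genes, which turned to 0.061 and 0.10 when libraries were scaled by total counts only, with means of 0.25 and -0.058. Under that scaling the median of the ubiquitin list also turned, from -0.073 to 0.041. They were -0.15 for MHC class II and co-stimulation and -0.36 for the type II interferon-stimulated genes, with means of -0.49 and -0.28. The MHC class II median turned to 0.021 without control replicate 1 and 0.11 without control replicate 3, and was -0.50 without control replicate 2. With the filter of at least 5 CPM it was 1.70 over 4 tested genes, and the adipogenic median was 0.29 over 10. The adipogenic median also turned to 0.020, 0.058 and 0.00086 without control replicate 1, control replicate 3 and immunoproteasome replicate 1. Camera ranked the MHC class II, type II interferon, heat shock and adipogenic lists higher.

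**Figure D4:**
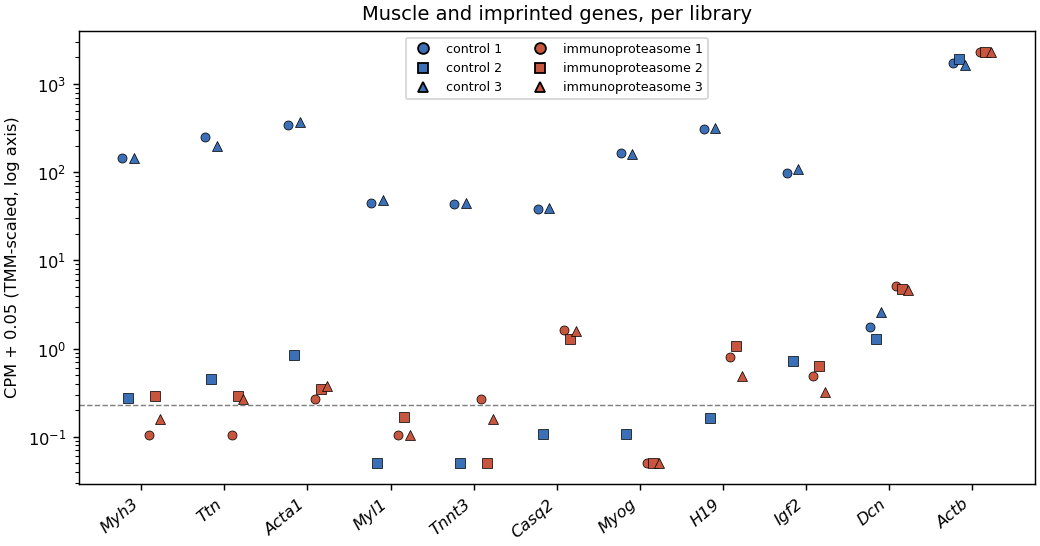
CPM plus 0.05 on a log axis for 11 genes in each of the 6 libraries, chosen after their values were seen, with control libraries in blue, immunoproteasome libraries in red and a dashed line at the highest level that 3 counts reach in a library. Skeletal muscle genes such as Myh3 and Ttn are present in control replicates 1 and 3 and near the line in control replicate 2 (blue square) and the immunoproteasome libraries.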

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

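The test of the result in this part was chosen only after the result was seen. Reads that overlapped no counted gene, which no comparison uses, took 12.3 ± 1.10% of the reads listed in the immunoproteasome libraries and 9.23 ± 1.46% in the controls (n = 3 each, exact two-sided permutation test, p = 0.1, the smallest possible). The share was 10.9% in control replicate 2, against 8.38 and 8.39% in control replicates 1 and 3.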

How the results depend on the processing

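The alternatives here were all planned. Between 8200 and 10605 genes passed under the other normalizations, filters, tools and left-out libraries, against 9413, and no gene called in both settings changed direction. Against a 1.5-fold change, 2374 genes rose and 1990 fell, fewer because that test asks for a larger effect. With the replicate number as a block, 4500 genes rose and 4542 fell and 8 lists passed. Whether the numbers mark pairs is not known. Deviations from the group mean correlated at -0.0536, -0.0414 and -0.0294 between libraries of the same number, and from -0.0203 to 0.0469 between those of different numbers. With 3 libraries per group, and control replicate 2 apart from the other controls, these values cannot decide it. Of the list tests, 8 passed with the preset correlation, 7 to 10 over the left-out libraries, 1 with an estimated correlation and 24 with fry, which asks another question. Over all settings, 2281 results for single genes stayed on their side of the threshold in the same direction, 29 lost their call, 3 gained it and 1 reversed. For lists these numbers were 323, 10, 23 and 7. The reversals were all far from the threshold, and the cause was not tested. Hist1h2bc moved from -0.10 to 0.012 on the log2 scale with scaling by total counts only. That scaling also turned the type II interferon list (adjusted p = 0.997), as leaving out control replicate 2 (0.366) or immunoproteasome replicate 1 (0.968) did, in a leave-one-out range from 0.366 to 0.990. The adipogenic list turned with the block (adjusted p = 0.858) and without control replicate 1 (0.974), in a leave-one-out range from 0.919 to 0.999. The constitutive subunits turned without control replicate 3 (0.980; range 0.919 to 0.999), and MHC class II without control replicate 2 (0.999; range 0.821 to 0.999). Genes below about 3 counts per library cannot be ranked by fold at this depth.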

Other observations

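In this part the tests on Arrdc4 with the amino-acid genes, and on the muscle genes, were set before the values they use were seen, the fits without control replicate 2 were planned as alternatives, and the other tests, with their use against an explanation, were chosen only after the result was seen. The lists described here were written after part of the values had been seen, so their counts are not independent evidence. Genes of the amino-acid response, targets of the transcription factor ATF4 outside the unfolded protein response list, fell in 27 of 28 cases, with a median log2 fold change of -1.52 (camera adjusted p = 2.97e-27; adjusted p = 0.00168 with an estimated correlation). The cystathionine lyase gene Cth fell from 163 ± 12.4 to 5.31 ± 0.638 CPM (n = 3 per group), Stc2 41.9-fold, the arginine transporter gene Slc7a1 4.91-fold and the mitochondrial folate enzyme gene Mthfd2 3.32-fold, while Ddit4 rose 1.15-fold, a call that was lost without control replicate 1 or 3 or immunoproteasome replicate 2, where 0 genes of the list were higher. Of 23 immediate early genes, which respond within minutes to growth factors and stress, 19 fell and 4 rose (camera adjusted p = 8.76e-07; adjusted p = 0.0123 with an estimated correlation). Fos fell 65.6-fold from 67.7 ± 11.1 CPM, Egr1 10.8-fold, Ier2 7.14-fold and Klf4 2.39-fold, and the 4 that rose were Fosl2, Egr3, Dusp5 and Klf2. The glucose-responsive genes Txnip and Arrdc4 both rose, Arrdc4 10.8-fold from 4.04 ± 1.39 to 43.9 ± 1.06 CPM.

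Of 17 genes of the Wnt pathway, 13 rose and 1, Wnt5a, fell 1.83-fold, or 2 without control replicate 2 (camera adjusted p = 0.0141; adjusted p = 0.498 with an estimated correlation). The secreted Wnt antagonist gene Frzb rose 4.11-fold, the transcription factor gene Tcf7 3.37-fold and the receptor gene Kremen1 1.52-fold. Imprinted genes were split, with 4 of 12 higher and 7 lower (camera adjusted p = 0.584), and without immunoproteasome replicate 1, 2 or 3 the number lower was 4 of 13. Among them were Plagl1 (20.8-fold), Cdkn1c (4.95-fold) and Igf2r (log2 fold change -0.68) lower and Peg10 2.49-fold higher. Of the 25 skeletal muscle contractile genes 5 were tested, with 2 lower (camera adjusted p = 0.584). The number lower was 1 when adjusted over the list alone, with the replicate block, and without control replicate 1 or 3 or immunoproteasome replicate 2. It was 0 of 1 tested with the filter of at least 5 CPM. Of the myogenic regulators 1 was tested, Mef2c, which fell 3.88-fold, a call that was lost with limma-voom (adjusted p = 0.0834). Without control replicate 2, 21 contractile genes and 7 regulators were tested and all of them fell. Myog, a regulator of muscle differentiation, stood at 165 and 160 CPM in control replicates 1 and 3, at 0.0567 CPM in control replicate 2 and at 0 in the immunoproteasome libraries. Igf2 stood at 97.9, 0.680 and 108 CPM in control replicates 1, 2 and 3, and H19 at 309, 0.113 and 314 CPM.

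The first pattern is that 9413 of 12477 genes differed between the groups. Of the 10 splits of the libraries into 3 and 3, 1, the real one, gave as many, the highest other count was 0 with edgeR (100 at an unadjusted p under 0.05, against 9628), and 10 splits are too few for a share under 0.05. For the 8 lists past the threshold, 7 of the 10 splits, including the real split, gave as many and the highest other count was 12. The number of lists therefore does not set the real grouping apart. The other splits mix both groups, so they are not free of the group difference and cannot test chance. Without control replicate 2, 10605 genes passed. An outlying library widens the spread within its group, so a rise was likely in advance and this count cannot decide whether that library is the source. Its distance is argued against as the source by the other controls. The median chi-square over that expected from counting was between 59.7 and 63.6 from control replicates 1 and 3 to the immunoproteasome libraries, against 1.70 between these controls. A candidate explanation is that the control cultures were short of nutrients or glucose when RNA was taken: the log2 fold change of Arrdc4 was 3.43 and 96.4% of the tested amino-acid genes were lower, values that this explanation needs. The amino-acid genes are ATF4 targets, and all 23 unfolded protein response genes fell as well. Their fall therefore cannot set a nutrient shortage apart from other stress that acts through ATF4. An effect of the immunoproteasome subunits themselves, or of any other difference between the cultures, also stays open as untested.

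The second pattern is the muscle genes of control replicates 1 and 3. Of the contractile genes with at least 1 CPM there, 21 of 21 were at least 4-fold lower in control replicate 2 (counts there of 3 or fewer were set to a floor of 3), so muscle-like cells in those cultures may be their source, by differentiation or from outside, and the most abundant of the 21 were Ttn (253 and 199 CPM) and Myh3 (143 and 145 CPM). Neb, among the 21, stood at 1.98 CPM in control replicate 2 and at a mean of 7.57 CPM in the immunoproteasome libraries. The muscle gene Myom2, outside that list, stood at 5 CPM or more in every control library. Not all muscle genes were therefore nearly absent from control replicate 2. A wrong label on control replicate 2, with the library belonging to the immunoproteasome group, is argued against, since its lowest Spearman correlation across genes with another control was 0.986 and its highest with an immunoproteasome library 0.887. A lower depth is also argued against, since its gene count was 96.5% of the mean of the other controls.

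The third pattern is that the 3 immunoproteasome catalytic subunits rose a few fold from low levels. A type I interferon response as the source is argued against, since the median log2 fold change of those genes was -1.30, and -1.56 without control replicate 2. A type II response, or induction through Irf1, which rose 2.11-fold, was not tested and stays open. Of the 18 type II genes 5 rose and 6 fell, and of 19 tested without control replicate 2, 5 rose and 10 fell. The low level of control replicate 2 is argued against as the only source of the rise. The median log2 fold change of the 3 subunits was 1.41 without that library, against 1.73 with it. The largest edgeR adjusted p of the 3 subunits without it was 2.86e-14. Leaving out an outlying control also narrows the spread within the group, so this p-value cannot decide the question. Whether introduced copies gave more reads than the table shows cannot be told apart from a small rise, because reads of an introduced coding sequence could have been counted with the gene or left out, and the 3 subunits together took 0.00642% of the gene counts in the immunoproteasome libraries. Expression of the subunits by design stays open as the biological explanation.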
